A study of Oryzias latipes with 12 samples.

How the data were processed

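Gene expression was measured in 12 samples of larval Japanese medaka, 3 in each of 4 groups kept in 0, 3, 30 or 100 ng/L of 17beta-estradiol for 7 days after hatching. Per the labels' protocols, fish were kept at 24 °C with 16 h of light and 8 h of dark in 2 L of water, with 90 fish in each aquarium, and each sample was a pool of 30 fish. The design text and the descriptions speak of whole fish, while a tissue label reads whole blood. The grinding protocol is that of frozen fish, and the samples are treated here as whole fish. Per the labels, only RNA with an integrity number of at least 9 was used, and 0.5 µg was amplified and labelled with the dye Cy3. The design text speaks of changes over time, and the samples used here are all of day 7. Groups and replicate numbers were taken from the sample titles.

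The deposited scanner files hold the intensity of each spot on a linear scale. Per the file headers, the intensity was extracted with Agilent Feature Extraction 9.5.3.1, with background subtraction and detrending within each array, while the submitters' processing notes name version 9.1. Flags for background, saturation and outliers, per the file headers, come from the same software. No step between arrays is recorded in these files. Each file holds 37815 spots, of which 1417 are control spots and 36398 are probes with distinct sequences. Of the probes, 98.6% are 60 nt long and the shortest has 55 nt. None was saturated on any array.

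A table of the whole series holds the authors' processed values, also on the linear intensity scale. Set against the scanner files, each deposited column is the scanner software's processed signal times 1 factor, which brings the median of its non-zero probes to 305.126, with a value of 0 for spots that were not significantly positive or were outliers. The scale is thus settled, no centring per probe was applied, and there is no ratio whose direction could be in doubt. The medians over all probes, zeros included, are given by the deposited columns' own replicate numbers 1 to 3. They were 215, 203 and 186 for the control, 236, 210 and 213 at 3 ng/L, 235, 211 and 227 at 30 ng/L, and 220, 220 and 252 at 100 ng/L. In each group the columns named replicate 1 and replicate 2 match each other's scanner file, so 8 of the 12 columns are exchanged within their group. Which of the 2 sources has the numbers right is not known. The exchange leaves group membership and the comparisons between groups as they are. Apart from these medians, replicate numbers are those of the scanner files.

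Probe, gene and systematic name are the same identifier in these files. Of 36398 identifiers, 18060 begin with TC and 18338 do not. None matched the gene table at hand, which is of assembly ASM223467v1, by gene identifier, accession or synonym. The 25 gene lists fixed before the data were examined therefore had 0 members, and no gene list was tested. No gene was named, and no result is given for any of those lists. The rule for a case without gene names, fixed before the data were examined, allows at most 2 probe identifiers each way. They are the 2 largest fitted rises and the 2 largest fitted falls at 100 ng/L among probes past the threshold whose 3 exposed arrays lie beyond the 3 controls.

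The values analysed are log2 of the processed signal minus the 75th percentile of that array's probes. Control spots were left out, and 39 outlier-flagged probe values were set to missing. A probe was tested if it was well above background on every array of at least 1 group, which kept 28925 probes. Of these, 26506 were well above background on all 12 arrays. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, so that the groups share an estimate of the spread. Moderated tests were two-sided, and p-values were adjusted after Benjamini and Hochberg over the tested probes, with a threshold of 0.05. The contrasts were each concentration against the control, 30 against 3 ng/L, 100 against 30 ng/L, a moderated F test over the 3 contrasts against the control, and a slope on the rank of the concentration. Fold changes are differences of group means on the log2 scale. Where a group has no array well above background, its level is only a bound. For sizes given as bounds, each array of the dimmer group that was not well above background took the higher of its own value and the lowest signal among probes well above background on that array. Such limits, given as "at least", hold for this processing and do not cover the spread between arrays. Chance agreement between concentrations was taken from 100 simulations of unchanged groups against shared controls. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

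The arrays lie on 5 slides scanned on 2 dates, per the file headers, with 4 arrays on the earlier date and 8 on the later one. Each group has replicate 1 on the earlier date. The first principal component held 52.4% of the variance and separated the dates, and the second, with 22.1%, followed the concentration. On the second, the 3 ng/L array that shared a slide with a control lay at −40.2, within the control range of −46.6 to −34.3. Replicates 2 and 3 of 3 ng/L, on a slide of their own, lay at −13.4. Slide and concentration are thus not told apart there for 3 ng/L. Between the dates 17852 probes differed, or 61.7% of those tested. Taking the date as a block lowered the median residual SD from 0.267 to 0.154. On the earlier date 1 slide held the control with 3 ng/L, and another held 30 with 100 ng/L. On the later date 1 slide held only controls, another only 3 ng/L, and another 30 with 100 ng/L. The control never shared a slide with 30 or 100 ng/L. Slide as a fixed block could therefore be fitted only for 3 ng/L against the control and for 100 against 30 ng/L, and slide was also taken as a random block with an estimated correlation of 0.116.

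The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means correlated between same-numbered arrays of different groups at r = 0.484 to 0.819, above the bound of 0.1 set for pairing. Numbers 2 and 3, which share a scan date, also correlated across groups at 0.356 to 0.686. Differences of number 2 minus number 3 correlated between groups at −0.047 to 0.248. The numbers thus pass the bound, but mostly through the scan dates. Within the later date numbers 2 and 3 showed little pairing of their own. The results with the replicate number as a block and with the scan date as a block are printed beside those without.

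The fits were tested on simulated data with the date effects and residual SDs of the 28902 complete probes, in which 200 probes were changed at 100 ng/L. Without a block, 36% of 2-fold, 76% of 4-fold, 100% of 10-fold and 100% of 100-fold changes were recovered, with 0 false calls. With scan date as a block 76%, 92%, 100% and 100% were recovered, and 6.6% of the calls were false. The simulated arrays had date effects and independent noise alone. These shares therefore do not cover slide or aquarium effects, or spreads that differ between groups. Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes, a filter on all 12 arrays, the series value table with zeros at its lowest non-zero value, outliers kept, each array left out, blocks for replicate number, slide and scan date, limma's trend and robust options, array weights, fits of only the 6 arrays compared, a 2-fold minimum and a slope on log10 of the concentration plus 1. The fits of the later date alone, of slide as a random block and without GA-repeat probes were added after the data were seen. Two-sided exact permutation tests of 3 against 3 single values cannot go below p = 0.1, so no such test is given.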

Results

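Larval Japanese medaka (Oryzias latipes), a small freshwater fish, were kept for 7 days after hatching in water with 0, 3, 30 or 100 ng/L of 17beta-estradiol, the main estrogen of vertebrates. RNA of whole fish was hybridised to 1-colour oligonucleotide arrays with 36398 probes. Each of the 4 groups held 3 arrays, and each array carried the RNA of a pool of 30 fish. Between 27707 and 31456 probes per array were well above background. The 12 arrays were scanned on 2 dates. Replicate 1 of each group was scanned on the earlier date and replicates 2 and 3 on the later one. Each aquarium held 90 fish, as many as the 3 pools of a group, so the pools of a group may come from 1 aquarium. The p-values then measure only the spread between such pools. The number of arrays limits the precision of every value below. The probes carry sequence identifiers and no gene names, so results are given by probe.

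The 100 ng/L group was set against the unexposed control to ask which transcripts the highest concentration changed. At 100 ng/L, 166 probes rose and 114 fell among the 28925 tested (limma, adjusted p under 0.05). With the dimmer group's arrays set at their bound where they were not well above background, 110 of the 166 probes rose at least 2-fold, 44 at least 10-fold and 29 at least 100-fold. Of the 114 probes that fell, 59 fell at least 2-fold and 10 at least 10-fold in the same way. The 3 exposed arrays lay beyond the 3 control arrays for each of the 280 probes. Such a separation was shown by 16.4% of all tested probes, and by 7.0% at 3 ng/L. Chance gives it for 10% of probes with 3 exchangeable arrays against 3, while here each group held arrays of both scan dates. In 40 of the 166 raised probes no control array was well above background and in 20 only some were, so that the control level is a bound there. Of the fallen probes, 3 had no exposed array well above background.

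Probe TC61341 had the largest fitted difference, though which rise was the largest is not known where control levels are bounds. Its sequence is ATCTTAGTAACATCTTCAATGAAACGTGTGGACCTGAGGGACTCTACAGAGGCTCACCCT. Its log2 signal relative to the array's 75th percentile was −6.07 ± 0.32 (SD, n = 3) in the controls and 5.75 ± 1.83 (SD, n = 3) at 100 ng/L. The fitted difference was 11.82 (SE 1.499, limma adjusted p = 0.00674). Of the 3 control arrays, 1 measured this probe well above background, and with the other 2 at their bound the rise was at least 11.78 on the log2 scale, or 3522-fold. Probe TC52966, with the sequence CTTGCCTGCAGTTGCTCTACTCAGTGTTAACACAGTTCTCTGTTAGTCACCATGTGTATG, was well above background on all 3 controls. It rose from −5.09 ± 0.71 to 5.98 ± 1.47 (SD, n = 3 each), by 11.07 (SE 1.40) or 2147-fold, with limma adjusted p = 0.00674. On the earlier scan date the control array was not well above background for TC61341, so its rise there was at least 13.52 on the log2 scale. On the later date, where 1 of 2 control arrays measured it, the rise was at least 10.92. That of TC52966 was 11.94 on the earlier date and 10.63 on the later one.

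**Figure D1:**
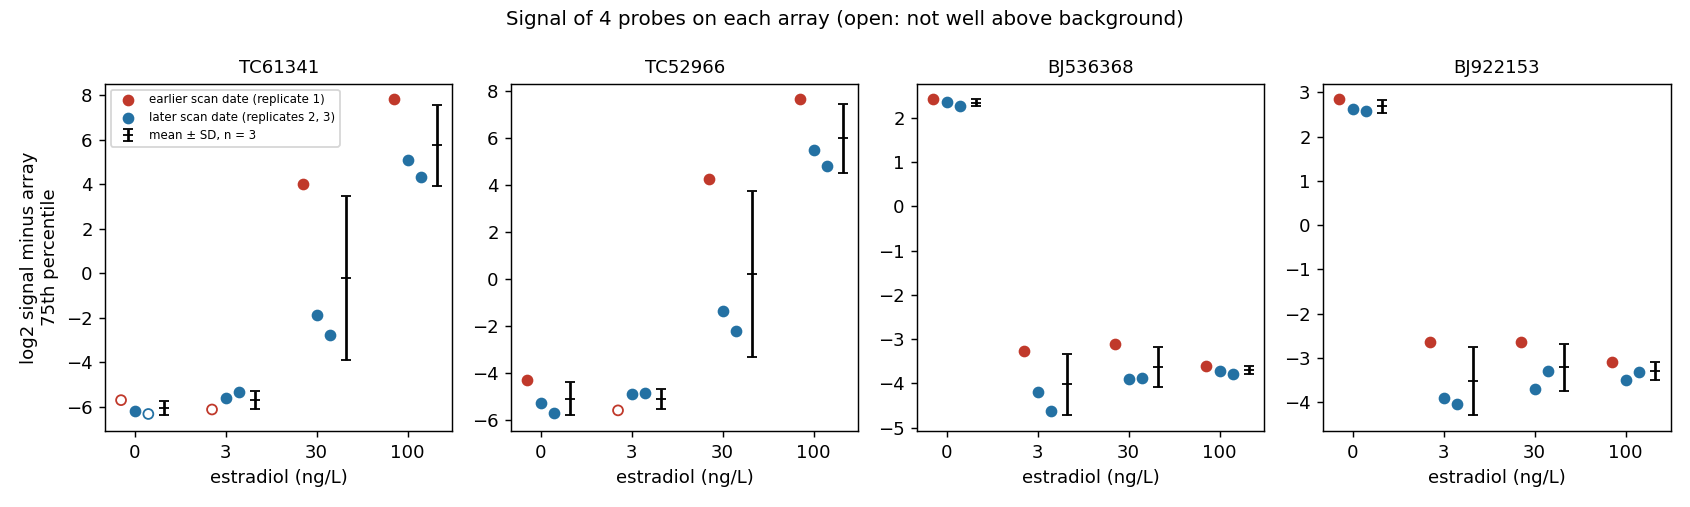
Signal of 4 probes on each of the 12 arrays by estradiol concentration, as log2 signal minus the array's 75th percentile; colours mark the scan date, open points were not well above background, and bars give the mean ± SD of 3 arrays. TC61341 and TC52966 lay near −6.07 and −5.09 in the controls and near 5.75 and 5.98 at 100 ng/L, where 2 of the 3 control points of TC61341 are open, while BJ536368 and BJ922153 were high in the controls alone.

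In the fit 48 probes rose by 10-fold or more at 100 ng/L, here called strongly raised, and 44 of them also did with control levels at their bound. These 48 formed 43 groups that shared no stretch of 20 nt. With control levels below background at their bound, their median log2 rise was at least 8.56 on the earlier scan date and at least 6.64 on the later one. The 11 that all 3 control arrays measured had medians of 9.15 and 9.68. The 101 fallen probes with no alternating GA run of 8 nt or more had a median change of −0.97 on the log2 scale, and 46 of them fell at least 2-fold. The balance of rises and falls moved with the processing. Against 166 rises and 114 falls, quantile normalization gave 157 and 163, scaling to the median 127 and 138, and the values deposited for the series 159 and 52. Normexp background correction gave 92 and 91, and the filter on all 12 arrays 100 and 103. The scaling of those deposited values put the median of all probes at 0.19.

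With scan date as a block, 1477 probes rose and 1368 fell at 100 ng/L, and all 280 probes called without it were among them. The replicate number as a block gave 1252 rises and 1201 falls, the later scan date alone 1395 and 1269, and slide as a random block with scan date 961 and 913. The earlier date held 1 array per group and gave no test of its own. No slide held the control with 30 or 100 ng/L, so slide is not fully told apart from concentration in these counts. Without the block the count moved when single arrays were left out. Each such fit holds the scan dates in unequal shares between groups, so a single array is not told apart from the dates. It was 72 without control replicate 2, 67 without control replicate 3, 179 and 165 without 30 ng/L replicates 2 and 3, and 104 and 80 without 100 ng/L replicates 2 and 3.

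**Figure D2:**
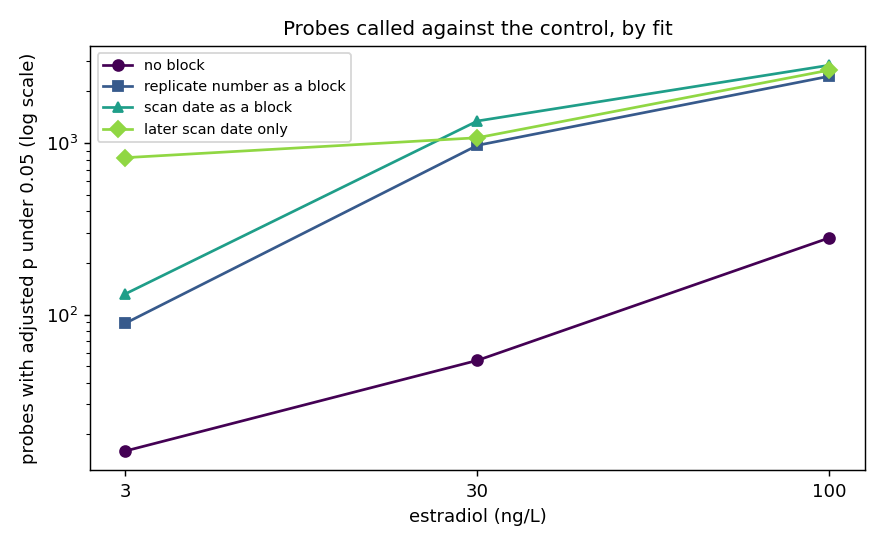
Number of probes with limma adjusted p under 0.05 against the control (log axis) at 3, 30 and 100 ng/L in 4 fits. Without a block the counts were 16, 54 and 280, and with scan date as a block they were 132, 1345 and 2845.

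At 30 ng/L, 38 probes rose and 16 fell. In 8 of the 38 rises no control array was well above background. With control levels at their bound, 28 rose at least 2-fold and 3 at least 10-fold. Among the 29 that all 3 control arrays measured, the rises reached 6.86 on the log2 scale, with a median of 1.27. Of the 38 probes, 32 had also risen at 100 ng/L, where 0.218 would be shared by independent lists. All 16 probes that fell had also fallen at 100 ng/L, against 0.0631 for independent lists. Both comparisons use the same controls, which adds to such overlap. The 30 and 100 ng/L arrays also shared slides that held no control, which may add to it. The 2 named rising probes did not pass the test at this concentration. TC61341 differed from the control by 5.85 (SE 1.499, limma adjusted p = 0.19) and TC52966 by 5.30 (SE 1.40, limma adjusted p = 0.205). Their 3 arrays were far apart, with an SD of 3.70 for TC61341 and 3.51 for TC52966. On the earlier scan date TC61341 was at least 9.72 above its control, and on the later date at least 3.86. With scan date as a block the adjusted p was 0.0255 for TC61341 and 0.0271 for TC52966.

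The 48 strongly raised probes were also set against the control at 30 ng/L on each scan date. The control array of the earlier date was well above background for 21 of them, and both of the later date for 11. With control levels at their bound, 39 of the 48 were at least 10-fold above the control at 30 ng/L on the earlier date and 18 on the later one, where 7 had no exposed array well above background. Such lower limits do not show on which date a rise was the larger. In the 11 probes that all 3 control arrays measured, the rise at 30 ng/L was the larger on the earlier date for 10, with medians of 6.73 and 5.72. At 100 ng/L it was so for 6 of the 11. Limma's interaction of dose and date was called for 4 of the 11 at 30 ng/L and for 1 at 100 ng/L. The earlier date has 1 array per group there and all 4 residual degrees of freedom come from the later date, so the single arrays are assumed to vary like the later ones, and a date is not told apart from a single pool. Without a block 6 of the 48 probes were called at 30 ng/L, and with scan date as a block 35 were.

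**Figure D3:**
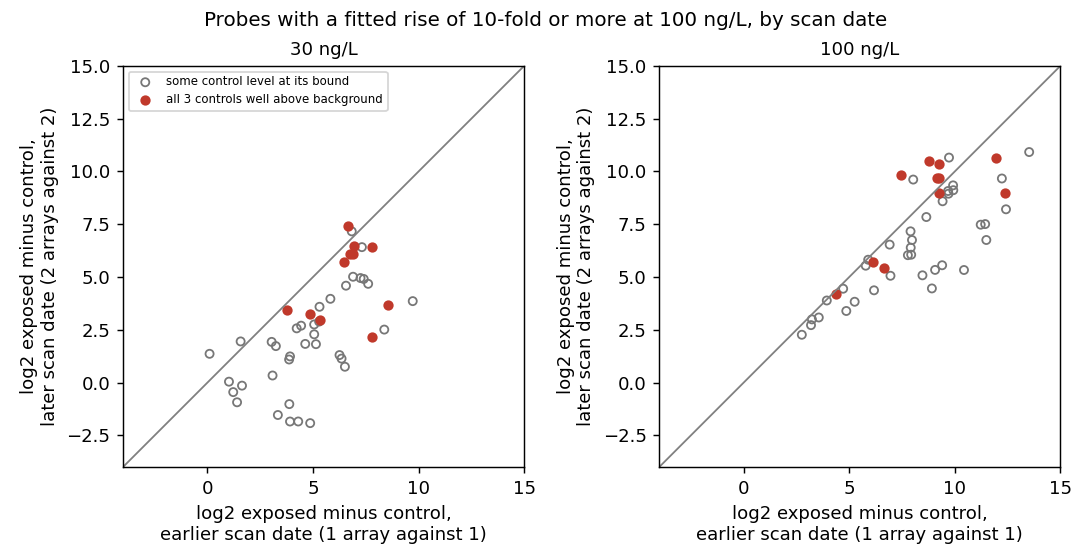
Log2 exposed minus control of the 48 strongly raised probes, on the earlier scan date (horizontal) against the later one (vertical), at 30 and at 100 ng/L; each point is a probe, the line marks equal values, and open points have 1 or more control arrays at their bound, so that their place against the line is not known. Of the 11 filled points, 10 lie below the line at 30 ng/L and 6 at 100 ng/L.

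Taking scan date as a block, 725 probes rose and 620 fell at 30 ng/L, and all 54 probes called without it were among them. The replicate number as a block gave 533 rises and 437 falls, the later date alone 632 and 442, and slide as a random block with scan date 381 and 290. Quantile normalization gave 28 rises and 20 falls and scaling to the median 26 and 19, in place of 38 and 16. Normexp background correction gave 17 and 17, and limma's trend and robust options 41 and 29. The count of 54 held within 1.5 times in 1 of the 12 fits that left out an array, that without 100 ng/L replicate 1, with 39. The balance turned in several of them, which also hold the scan dates in unequal shares between groups. Without control replicates 1, 2 and 3 there were 13, 3 and 2 rises and 15, 11 and 9 falls. Without 3 ng/L replicates 1, 2 and 3 there were 136, 12 and 12 rises and 78, 13 and 11 falls. Without 30 ng/L replicates 1, 2 and 3 there were 5, 2 and 7 rises and 10, 8 and 9 falls, and without 100 ng/L replicates 2 and 3 there were 8 and 15 rises and 12 and 12 falls. No filter on dim probes gave 9 rises and 11 falls, and only the 6 arrays compared 8 and 11.

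At 3 ng/L, 5 probes rose and 11 fell. Of the 5 rises, 4 lay between 1.13 and 2.19 on the log2 scale, and for the other no control array was well above background and the bound gives no fold. The rises moved when single arrays were left out, which also leaves the scan dates in unequal shares between groups. They numbered 2, 1 and 0 without control replicates 1, 2 and 3, and 27, 1 and 0 without 3 ng/L replicates 1, 2 and 3. Without 30 ng/L replicates 1, 2 and 3 they numbered 4, 3 and 2, and without those of 100 ng/L 7, 3 and 3. The falls numbered 16 without 3 ng/L replicate 1 and 9 to 12 in the other 11 fits. A fit of only the 6 arrays compared called 0 rises and 9 falls. The 5 probes that rose in the fit of all 12 arrays had also risen at 30 ng/L, and 3 had risen at 100 ng/L. Without a block, 0 of the 48 strongly raised probes passed the test at 3 ng/L, and with scan date as a block 1 did. The 10 of them that all 6 arrays measured had differences of −0.11 to 2.27, with a median of 0.53. TC61341 differed from the control by 0.38 at 3 ng/L (95% interval −2.95 to 3.71) and TC52966 by −0.02 (SE 1.40). TC61341 was well above background on 2 of 3 arrays at 3 ng/L and 1 of 3 controls. TC52966 was so on 2 of 3 arrays at 3 ng/L and all 3 controls. Both differences thus hold levels that are bounds. The SE and the interval rest on a spread shared by the 4 groups. For TC61341 the SD was 3.70 at 30 ng/L and 1.83 at 100 ng/L, but 0.40 at 3 ng/L and 0.32 in the controls. The width of its interval thus mostly reflects the higher concentrations and does not tell what rise at 3 ng/L stays possible.

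The 11 probes that fell at 3 ng/L had also fallen at 30 and at 100 ng/L. All 11 carry a run of alternating G and A, of 11 to 35 nt. Such a run of 8 nt or more is present in 107 of the 28925 tested probes, or 0.37%, and its frequency among the 11 differed from that among the others (two-sided Fisher's exact test, p = 1.05e-27, on probes grouped after their values were seen). With exposed levels below background at their bound, the median change of the 11 was −5.34 at 3 ng/L, −5.08 at 30 ng/L and −5.06 at 100 ng/L. BJ536368 (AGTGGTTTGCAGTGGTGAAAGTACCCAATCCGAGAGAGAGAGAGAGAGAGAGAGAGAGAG) stood at 2.35 ± 0.07 (SD, n = 3) in the controls and at −4.03 ± 0.70 at 3 ng/L, a change of −6.37 (SE 0.32, limma adjusted p = 1.88e-05). At 100 ng/L its change was −6.05 (SE 0.32, limma adjusted p = 3.17e-05). BJ922153 (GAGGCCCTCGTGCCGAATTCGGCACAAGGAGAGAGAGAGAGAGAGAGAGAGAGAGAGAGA) changed by −6.21 (SE 0.36, limma adjusted p = 4.28e-05) at 3 ng/L and by −5.98 (SE 0.36, limma adjusted p = 5.05e-05) at 100 ng/L. On the slide that held a control and a 3 ng/L array, the median change of the 11 was −5.14, or −4.59 with levels below background at their bound.

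**Figure D4:**
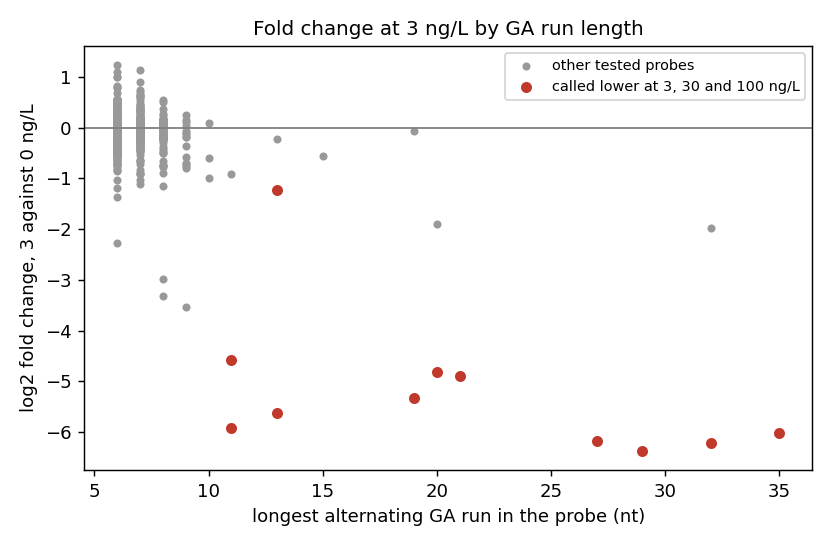
Log2 fold change at 3 ng/L against the control (vertical) by the longest alternating GA run in the probe (horizontal, nt), for tested probes with a run of 6 nt or more. The 11 probes called lower at 3, 30 and 100 ng/L (red) have runs of 11 to 35 nt.

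Probes with a GA run of 8 nt or more were then left out, a setting chosen after the data were seen. Without a block, no probe was then called at 3 ng/L by limma. Of all tested probes 1224 had an unadjusted p under 0.05, below the share of 0.05 that chance gives. With scan date as a block 4026 did. Without it the date differences stay in the error term, so a count below that share does not show an absence of change. The 5 probes that had risen carry no GA run of 8 nt or more, and their fitted changes of 1.13 to 2.19 stayed as they were. Their adjusted p, between 0.0153 and 0.0321 before, lay between 0.0912 and 0.102, as the adjustment runs over fewer small p-values. With scan date as a block as well, all 5 passed. The same setting without a block left 21 rises and 2 falls at 30 ng/L, and 164 rises and 101 falls at 100 ng/L. When scan date was a block, 76 probes rose and 56 fell at 3 ng/L, and leaving out the GA-repeat probes as well gave 62 rises and 27 falls. The replicate number as a block gave 48 rises and 41 falls, and slide as a random block with scan date 37 and 33. The later date alone gave 476 and 346. There the controls lay on 1 slide and the 3 ng/L arrays on another, so slide and concentration are not told apart. Slide as a block gave 96 and 105, a fit in which this contrast rests on the 1 slide with both groups, 1 array against 1, and takes its spread from other slides. Without a block the count of 16 was 10 without control replicate 3, 43 without 3 ng/L replicate 1 and 9 without 3 ng/L replicate 3.

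The concentrations were compared with each other to test whether they differed. Without a block limma called 0 probes between 3 and 30 ng/L and 0 between 30 and 100 ng/L. An unadjusted p under 0.05 was found for 744 and 446 probes. Both counts lie below the share of 0.05 that chance gives among the 28925 tested. With scan date as a block the counts were 2939 and 1746. Without it the date differences stay in the error term, so counts below that share do not show that the concentrations act alike. When scan date was a block, 36 probes were higher at 30 than at 3 ng/L and 0 were lower, with a median difference of 3.81 on the log2 scale with 3 ng/L levels below background at their bound. Of these 36 probes, 31 belonged to the 48 strongly raised ones. On each scan date, 35 of the 36 were higher at 100 than at 30 ng/L. Between 30 and 100 ng/L the same fit called 27 probes higher and 3 lower at 100 ng/L, and 23 of the 27 belonged to the 48. The 48 were chosen by their rise on the same 100 ng/L arrays, which favours this overlap. The replicate number as a block gave 34 probes between 3 and 30 ng/L and 22 between 30 and 100 ng/L. The later date alone gave 37 and 88. Slide as a block could be fitted between 30 and 100 ng/L and gave 91 probes, and within the slide that held 2 arrays of each of these groups 77 were called, 66 of them higher at 100 ng/L. Without 30 ng/L replicate 1 the fit without a block called 5 probes between 30 and 100 ng/L. Without 30 ng/L replicate 3 it called 1 in each comparison, and without 3 ng/L replicate 1 it called 1 between 3 and 30 ng/L.

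Concentration dependence was tested over all 4 groups. The moderated F test found 103 probes that differed among the groups, and 100 of them were also called at 100 ng/L. They included all 11 GA-repeat probes that fell at each concentration and 35 of the 48 strongly raised probes. A slope on the rank of the concentration was called for 366 probes, 206 rising and 160 falling, and 275 of them were also called at 100 ng/L. With scan date as a block 1231 probes differed among the groups and 3777 had a slope, and with the replicate number as a block 920 and 3298 did. Quantile normalization gave 186 rising and 247 falling slopes, scaling to the median 167 and 223, and the values deposited for the series 179 and 72. Normexp background correction gave 133 and 142, and the filter on all 12 arrays 125 and 144. The F count was 62, 34 and 33 without control replicates 1, 2 and 3, and 194, 52 and 43 without those of 3 ng/L. It was 68 and 67 without 30 ng/L replicates 2 and 3, and 52, 33 and 44 without 100 ng/L replicates 1, 2 and 3. The slope count was 128 and 117 without control replicates 2 and 3, 188 without 30 ng/L replicate 3, and 148 and 124 without 100 ng/L replicates 2 and 3. These fits too hold the scan dates in unequal shares between groups.

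Fold changes of different concentrations were compared across 28902 probes, which are not independent replicates. Pearson's r was 0.822 between 30 and 100 ng/L, 0.639 between 3 and 30 ng/L and 0.486 between 3 and 100 ng/L. Simulated unchanged groups set against shared controls gave 0.499, 0.500 and 0.501. The covariance between 30 and 100 ng/L was 0.174, against 0.020 in the simulation. Between 3 and 30 ng/L it was 0.0757 and between 3 and 100 ng/L 0.0774, each against 0.020. With 3 controls, no split leaves 2 arrays in each part, so part of the excess may come from the shared controls. The 30 and 100 ng/L arrays also shared slides on which no control lay. The simulation leaves slides out, so part of the excess between 30 and 100 ng/L may come from them.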

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

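The fits of the later scan date alone, of slide as a random block and without GA-repeat probes were chosen after the data were seen. The list below gives, in this order where fitted, the probes called at 3, 30 and 100 ng/L against the control, between 3 and 30 ng/L, between 30 and 100 ng/L, among the 4 groups, and with a slope, against 16, 54, 280, 0, 0, 103 and 366. Replicate number as a block, which pairs the arrays mostly by scan date, gave 89, 970, 2453, 34, 22, 920 and 3298. Scan date as a block gave 132, 1345, 2845, 36, 30, 1231 and 3777. The later date alone gave 822, 1074, 2664, 37, 88, 1092 and 2636. On that date neither the controls nor the 3 ng/L arrays shared a slide with another group. All of these counts but that between 30 and 100 ng/L thus also set slide against slide. Slide as a random block with scan date gave 70, 671, 1874, 35, 55, 592 and 2214. Slide as a block gave 201 at 3 ng/L, where only 1 slide holds both groups with 1 array each and other slides give the spread, and 91 between 30 and 100 ng/L. It could not be fitted for 30 or 100 ng/L against the control, the F test or the slope. Array weights gave 1377, 2439, 4430, 47, 164, 2912 and 4547, with weights of 0.217 to 0.242 on the 4 arrays of the earlier date and of at least 1.055 on the others. The blocks lowered the residual SD, since the date differences leave the error term.

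Fits without a block moved some counts downwards. No filter on dim probes gave 20 at 30 ng/L, 178 at 100 ng/L, 64 among the groups and 239 with a slope. Normexp background correction gave 34 at 30 ng/L and 183 at 100 ng/L. The filter on all 12 arrays gave 49 among the groups, with fewer probes tested. Only the 6 arrays compared gave 9, 19 and 86 at the 3 concentrations. A 2-fold minimum gave 181 at 100 ng/L. Between 3 and 30 ng/L, normexp, median scaling, the series value table and the trend and robust options each gave 1 in place of 0. Leaving out GA-repeat probes gave 0 at 3 ng/L and 23 at 30 ng/L. Except where a construction is named, the cause was not tested.

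Leaving out each array in turn gave 9 to 43 probes at 3 ng/L, 10 to 214 at 30 ng/L, 67 to 419 at 100 ng/L, 0 to 1 between 3 and 30 ng/L, 0 to 5 between 30 and 100 ng/L, 33 to 194 among the groups and 117 to 401 with a slope. In these fits, which have no block, the scan dates are in unequal shares between groups, so the counts do not tell single arrays from the dates. Of 189 counts under alternatives, 95 stayed within 1.5 times. The 4 named probes kept their direction and their side of the threshold in 279 of 294 values. In 10, all of rising probes at 30 ng/L, they passed the threshold that they had missed. In 5, TC52966 at 3 ng/L went from −0.02 to a value above 0, past the threshold in none of these 5. It was 0.11 in the series value table, 0.50 with array weights, 0.61 on the later date alone, 0.37 without control replicate 1 and 0.22 without 3 ng/L replicate 1, in a range of −0.32 to 0.37 over the arrays left out, and the cause was not tested. At 100 ng/L the fitted rise of TC61341 ranged from 9.83 to 12.53, with adjusted p from 4.79e-06 to 0.0452, and the change of BJ536368 from −6.11 to −5.48, with adjusted p from 9.65e-09 to 0.000591. The correlation of fold changes between 30 and 100 ng/L ranged from 0.684 to 0.8504, between 3 and 30 ng/L from 0.500 to 0.753, and between 3 and 100 ng/L from 0.406 to 0.623. Gene list shifts were not run, as no probe could be matched to a gene. Levels near background are bounds, which limits the folds of strongly raised probes.

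Other splits of the arrays were compared with the real groups. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and in 4 of them all 3 replicate numbers are parted, as in the real split. The real counts were 16, 54 and 280 against the control, where 1 split of the 10 gave as many, and the highest of the others was 0, also among those that part all 3 numbers. Between 3 and 30 ng/L and between 30 and 100 ng/L the real count was 0, and all 10 splits gave 0. For the F test, 5 of 100 splits gave as many as the real 103, up to 5306. For the slope 7 of 100 gave as many as the real 366, up to 11746. By the rule set beforehand chance is thus not excluded for these counts. These splits, however, mix the scan dates, which the real groups hold in equal shares, so they do not test the groups alone. The splits with such high counts point to the scan dates. Of the 4 other splits in the F test, 3 put 3 or more arrays of the earlier date into 1 group, and of the 6 for the slope 5 did. Splits with 1 earlier array per group, the real one included, numbered 24 for the F test and 21 for the slope. Among them the highest other F count was 11 and the highest other slope count 0, so no other reached the real counts. With scan date as a block and regrouping within dates, 1 split of 100, the real one with 1231, reached that count. The highest other gave 477, so that chance regrouping of single arrays is argued against there. Slide and aquarium stay open. On the later date 1 slide held only controls and another only 3 ng/L, which the regrouping breaks up, and with slide as a random block the count was 592. The pools of a group may come from 1 aquarium, which the regrouping would break up as well.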

Other observations

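In the tests below, those of batch on the GA-repeat probes, of the dynamic range, of exchanged labels and of array scaling at 30 ng/L were chosen only after the result was seen. Of the 48 strongly raised probes, 23 had no control array well above background, and 11 had all 3. Among probes called with scan date as a block, 66 of the 76 raised at 3 ng/L were also raised at 30 ng/L, where independent lists would share 1.9. At 100 ng/L 64 of the 76 were also raised, against 3.88 for independent lists. The comparisons share their controls, which adds to this overlap.

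The fall of 11 GA-repeat probes at each concentration was as deep at 3 as at 100 ng/L, with a median difference of 0.23 between these on the log2 scale. To ask about a slide or scan batch, the slide that held a control and a 3 ng/L array was used. The median change there was −5.14, or −4.90 over the 9 probes measured on both arrays. The 11 probes were chosen by a fit that held these same arrays, 1 against 1. A large change there was thus favoured by the choice, and a slide batch is not settled by this 1 pair. Each scan date held arrays of all 4 groups. The median level of the 11 was 2.42 in the control of the earlier date and 2.35 and 2.28 in those of the later. In exposed arrays it was −2.65 to −3.09 on the earlier date and −3.36 to −4.08 on the later. A scan date effect common to all groups is thus argued against. The motif AATTCGGCAC, part of an adaptor common in cDNA cloning, is argued against. Of the 11 probes 1 carries it, and 36 tested probes with it and no GA run of 8 nt or more had a median change of −0.0231. Other linker sequence, one with a GA run included, stays open. Cross-hybridisation of a repeat-bearing RNA with GA runs is a candidate explanation, since 5 other tested probes with runs of 12 nt or more had a median change of −0.55 at 3 ng/L, against −0.02 for 58 probes with equally long runs of other dinucleotides. These 5 are few, their median was −0.24 at 30 ng/L and −0.01 at 100 ng/L, and whether such an RNA in the controls answers to estradiol or marks the control aquarium stays open.

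Of tested probes with a run of alternating C and T of 12 nt or more and no GA run of 8 nt or more, the 14 had a median change of 0.47 at 3 ng/L and 0.60 at 100 ng/L, and 0 of them lay below 0 at 3 ng/L.

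Of the 11 strongly raised probes that all 3 control arrays measured, 10 rose more on the earlier scan date at 30 ng/L and 6 did at 100 ng/L, where the dates were thus near even. A narrower dynamic range on the later date is argued against by the spike-in slopes, whose ratio of later to earlier date was 0.994. Exchanged 30 and 100 ng/L labels are argued against too, since of the 36 probes called higher at 30 than at 3 ng/L with scan date as a block, a choice that ranks no probe by its 100 ng/L level, 97.2% were higher at 100 than at 30 ng/L on each date. Array scaling stays open, since the median date difference over all tested probes, −0.0107 at 100 ng/L, is largely set by the scaling itself, and scaling to the spike-ins gave 1.64 at 30 ng/L over the 11 in place of 0.80, with an SE of 0.662 from the spread of the spike-ins. The earlier date holds 1 pool per group, and it remains open whether the pools scanned on the earlier date came from another exposure or differed in their estradiol level, which no label tells and which may be biological.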
